A study of Mus musculus with 19 samples.

How the data were processed

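Total RNA from the hearts of 19 FVB/N mice was measured, 1 bead array per animal. Per the labels, RNA was extracted with Tri-reagent, converted to cDNA with a T7-linked oligo(dT) primer and labelled with Cy3. Each animal was wild type (WT) or a transgenic mouse, named CCM in the labels, without a working circadian clock in its cardiomyocytes. The animals had received a normal or a high fat diet for 16 weeks and were sampled at ZT 18, in the middle of the active phase. Groups were taken from the labels and held 5 WT and 5 CCM animals on the normal diet, and 4 WT and 5 CCM animals on the high fat diet. Every array came from a separate animal, so the spread within a group holds animal and array variation together.

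The authors deposited a table of average bead signals, which are intensities on a linear scale that were not normalized between arrays, per the file headers and the values themselves. Beside each intensity the authors deposited a detection p-value per probe and array. BeadStudio 3 is named in the submitters' processing notes, and its background settings are not given in the sources used here. A further table of the authors' normalized intensities, on a linear scale, held column medians between 98.2 and 98.3 and ranked the probes of each array as the unnormalized signals did (lowest rank correlation 1). Its normalization method is not given in the sources used here, and it served only as an alternative. Mean signal per array ran from 418.75 to 580.37, and 17117 to 18731 of the 46643 probes had a detection p under 0.05. Signal over background and the number of arrays limited the precision. Pearson correlations were taken over normalized log2 values of the 14762 genes tested. They were 0.969 to 0.994 between arrays of a group and 0.970 to 0.995 between arrays of different groups. At most 0.00214% of all probes held identical signals on any pair of arrays.

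Probe names came from the deposited tables and were updated through a table of mouse genes on assembly GRCm38.p6, used for names and for the order of neighbouring genes only. Of the probes, 26165 matched by transcript accession, 4619 by symbol and 3903 by an older symbol, 11951 kept the name in the file, and 5 of the 35 probes with a date in place of a symbol stayed unnamed. Background was corrected and arrays were quantile normalized with neqc in limma 3.58.1 (R 4.3.3), with an offset of 16 and background estimated from the detection p-values. Probes detected on at least 4 of the 19 arrays were kept (19840 probes), and each gene was represented by its detected probe with the highest mean, which gave 14762 genes. Values are log2 normalized signals. Fold changes of dim genes are understated on this scale.

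A linear model with a mean per group was fitted over all 19 animals with lmFit and eBayes (15 residual and 3.62 prior degrees of freedom). Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 14762 genes. A gene is called changed at an adjusted p under 0.05. Errors written after ± are standard errors of the fitted difference unless SD is named. Where no array of the dimmer group detected a gene, the fold is a lower bound: the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value among detected probes. Of 39 gene lists, 36 had at least 5 measured genes and were tested with camera at a preset correlation between genes of 0.01, with p-values adjusted over the 36 lists. The same test with a correlation estimated from the data was run beside it. The lists were written from general knowledge, apart from Dgat2 and Pdk4, which were placed in the clock-output list with knowledge of the study. Of the measured genes, 42 stood in more than 1 list.

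The groups, the model, the gene lists and most alternatives were fixed before the data were examined. So was the rule for the genes named: in each comparison the 6 largest increases and decreases among changed genes detected on every array of a group and carrying an official-style symbol, up to 4 members of each list with the smallest p, any member of the circadian clock and triglyceride synthesis lists, and Clock with all of its probes first. The text names 168 pairs of a gene and a comparison from that set, and some results that the rule would name are not reported here. Other background corrections and normalizations, the authors' normalized values, other detection filters, all probes, a trended and robust eBayes, array weights, fits of 2 groups and fits without each animal in turn were planned. The planned median scaling, limma's scale method, divides the log2 values of an array by a factor and so also changes their spread. Animal numbers were examined later, and fits with a block for animals numbered under 20 (10 animals) and over 20 (9 animals), fits within each part, fits without the 3 arrays of lowest mean signal and a normalization that shifts the log2 values of each array by a constant, to equal medians of detected probes, were added after seeing the data.

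The fitting steps were tested on simulated values for the 14762 genes with 200 genes changed. For the genotype effect on the normal diet, 40.3% of 1.41-fold, 91.0% of 2-fold and 100% of 4-fold changes were recovered. The shares were 37.3%, 97.0% and 100% for the genotype effect on the high fat diet, 35.8%, 92.5% and 100% for the diet effect in WT, and 50.8%, 95.5% and 100% for the diet effect in CCM. They were 10.4%, 79.1% and 93.9% for the interaction, 76.1%, 98.5% and 100% for the averaged genotype effect, and 67.2%, 95.5% and 100% for the averaged diet effect. Between 3.75% and 5.67% of the simulated calls were false. The simulated noise was normal and independent between genes and arrays, without the animal number structure described below. These shares may therefore not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.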

Results

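Gene expression was compared between hearts of wild-type mice and of CCM mice, FVB/N transgenics without a working circadian clock in cardiomyocytes, on 2 diets. The question was whether this clock governs triglyceride metabolism of the heart. Single arrays were available for 5 WT and 5 CCM animals on the normal diet and for 4 WT and 5 CCM animals on the high fat diet, all sampled at ZT 18 after 16 weeks of feeding. Because no other time of day was sampled, a changed level of a rhythmic gene cannot be told apart from a shifted or flattened daily rhythm. Likewise, a gene that did not differ at ZT 18 may differ at other times. Arrays detected 17117 to 18731 probes each. CCM mice are known to carry a transgene for a dominant-negative form of CLOCK, so the Clock signal checked the genotype labels. One Clock probe read 15.27 ± 0.18 (SD, n = 10) in CCM and 7.52 ± 0.86 (SD, n = 9) in WT hearts on the log2 scale, with no overlap between animals (CCM from 14.95, WT up to 8.39). A further Clock probe read 11.22 ± 0.14 against 10.73 ± 0.11 (SD). The remaining Clock probe was detected on no array. The first probe lay near the top of the signal range in CCM hearts (highest log2 value on any array 15.76), so that its folds are lower estimates.

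On the normal diet, the largest difference between CCM and WT hearts was in 1 Clock probe (at least 178-fold higher, 7.47 ± 0.36 log2, adjusted p = 5.06e-11). This probe stood for Clock because it had the highest mean over all arrays, which its CCM values raised. The other detected Clock probe, found on all 19 arrays and brighter in WT hearts, showed 0.47 log2. Ces1d, a carboxylesterase that hydrolyses triglyceride, was 9.86-fold lower (-3.30 ± 0.14 log2, adjusted p = 6.80e-12). Dgat2, which catalyses the last step of triglyceride synthesis, was 2.23-fold lower (-1.16 ± 0.10 log2, adjusted p = 3.11e-07), and Bdh1, a mitochondrial enzyme of ketone body use, was 4.50-fold lower (-2.17 ± 0.20 log2). Another bright Bdh1 probe showed -2.38, and a dim one detected on 5 arrays showed 0.09. Expression of Dbp, a clock-controlled transcription factor, fell by 1.99 ± 0.15 log2 (adjusted p = 8.80e-08). In all, 282 of 14762 genes changed by limma, 109 higher and 173 lower in CCM, and 71 of them changed at least 2-fold.

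The largest increases after Clock were the probes named AmpR (at least 14.6-fold) and AlkPhos (at least 10.4-fold), detected in all 10 CCM and none of the 9 WT hearts. They were followed by Mrln (1.83 ± 0.18 log2), which encodes the calcium pump inhibitor myoregulin, Slc17a7 (1.63 ± 0.22), a glutamate transporter, and Cntn5 (1.58 ± 0.10), a cell adhesion protein. The largest decreases after Ces1d were Cyp2b10 (-3.07 ± 0.29), a cytochrome P450, the lysosomal Laptm4a (-2.96 ± 0.13), Ano4 (at least 3.63-fold lower), and the amylases Amy1 (-2.23 ± 0.15) and Amy2a5 (-2.22 ± 0.12), neighbouring paralogs whose probes may share targets. Igf2bp2, an RNA-binding protein, was higher by 1.53 ± 0.10 log2 averaged over the diets.

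Of 18 measured core clock genes, 2 rose, 3 fell and 13 did not pass (5 rose and 7 fell adjusted over the list alone). Beside Clock, Arntl, which encodes its partner BMAL1, rose by 1.19 ± 0.16 log2 (adjusted p = 0.000116). The repressors Ciart (at least 2.09-fold lower), Per3 (-0.80 ± 0.16) and Cry2 (-0.77 ± 0.19, adjusted p = 0.0406) fell. Nr1d2 (-0.95 ± 0.29, adjusted p = 0.139), Nr1d1 (0.40 ± 0.13, adjusted p = 0.199), Per2 (-0.33 ± 0.18, adjusted p = 0.624) and Per1 (-0.11 ± 0.36, adjusted p = 0.989) did not pass. With a block on animals numbered under and over 20 Nr1d2 passed (-1.10, adjusted p = 0.00160), while another probe of it showed -0.29 without the block. As a list the core clock genes did not pass in camera (adjusted p = 0.385), and their median (-0.22) and mean (0.22) differed in sign. The list includes Clock itself, whose 7.47 log2 raised the mean and counted against a lower list. These list values therefore do not describe the other members alone. The call of Cry2 was lost without 11 single animals of the 19 (adjusted p up to 0.120, without CCM normal replicate 1).

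**Figure D1:**
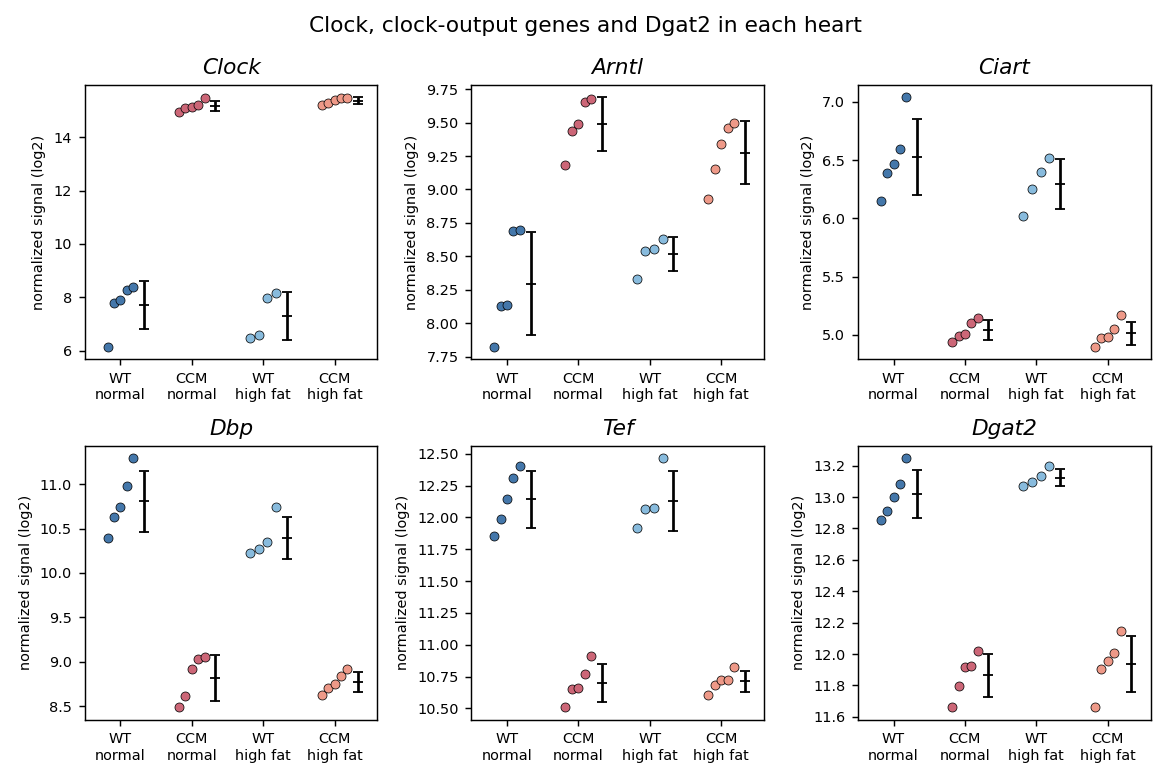
Normalized signal (log2, vertical axes) of 6 genes in each of 19 hearts by genotype and diet, with the mean and SD of each group beside the points. Clock and Arntl lay higher and Ciart, Dbp, Tef and Dgat2 lower in all CCM than in all WT hearts of either diet.

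PAR bZIP factors and clock-output genes were the list with the smallest p. Of 12 measured members, 4 fell, none rose and 8 did not pass (6 fell adjusted over the list alone), with a camera adjusted p of 2.66e-13 and adjusted p = 0.000629 with an estimated correlation. Members that fell were Dbp, Tef, a related factor (-1.44 ± 0.11), Nampt, the NAD salvage enzyme (-1.30 ± 0.18), and Dgat2. Usp2, a deubiquitinase, stood at -0.67 ± 0.19 (adjusted p = 0.0948). Dimmer probes of Tef showed -1.30 and -0.34. Dgat2 and Pdk4 were placed in this list with knowledge of the study. The 11 members without Dgat2 gave an unadjusted p of 2.94e-05 with an estimated correlation.

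Among 15 measured triglyceride synthesis genes, Agpat3, an acyltransferase, rose (0.44 ± 0.07), Dgat2 fell and 13 did not pass, with the same counts adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.327). Pnpla3, a lipid droplet protein, rose by 0.82 ± 0.18 (adjusted p = 0.0162). In other lists Thrsp, a lipogenic regulator (-1.18 ± 0.27), Pmvk of the mevalonate pathway (-0.65 ± 0.11), the pyruvate dehydrogenase kinase Pdk1 (-0.46 ± 0.10) and the glutathione transferase Gsta1 (-0.81 ± 0.19) fell. Pik3r1, a regulatory subunit of PI3 kinase, fell by 0.59 ± 0.10, and Trib3, a pseudokinase, rose by 0.50 ± 0.12. Oxct1, a ketolytic enzyme, stood at -0.31 ± 0.08 (adjusted p = 0.0504, 0.0378 without CCM normal replicate 5, and 0.0347 with a block on animal numbers). Ketone and branched-chain amino acid catabolism (21 measured, 1 fell, none rose, 3 fell adjusted over the list alone) was lower at an adjusted p of 0.0430. It had adjusted p = 0.387 with an estimated correlation, and 0.185 without WT normal replicate 2, 1 of 4 animals whose omission ended the call. Glucose and glycogen use (34 measured, 1 fell, none rose, likewise adjusted over the list alone) was lower at 0.00389, with adjusted p = 0.362 with an estimated correlation. Calls were lost without single animals for Thrsp (5 animals, adjusted p up to 0.0710 without WT normal replicate 1), Trib3 (6, up to 0.0921 without CCM normal replicate 3), Gsta1 (7, up to 0.0829 without CCM normal replicate 1) and Pnpla3 (2, up to 0.0548 without WT normal replicate 5).

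Genes of cardiac stress and hypertrophy moved upward: of 24 measured, 4 rose, none fell and 20 did not pass (5 rose adjusted over the list alone), with a camera adjusted p of 0.000156 and adjusted p = 0.172 with an estimated correlation. They were the calcineurin inhibitor Rcan1 (0.97 ± 0.11), the intercalated disc protein Xirp1 (0.55 ± 0.11), the cell cycle inhibitor Cdkn1a (1.51 ± 0.27) and the pyrimidine salvage kinase Uck2 (0.56 ± 0.12). The channel genes Hcn2 (0.96 ± 0.12) and Kcne1 (1.10 ± 0.19) and the myosin-binding protein gene Mybpc2 (1.18 ± 0.16) also rose. The early gene Ier3 fell by 0.93 ± 0.13. The mitochondrial genes Mrpl22 (-0.75 ± 0.10) and Uqcr10 (-0.27 ± 0.07) fell and Mrps34 rose (0.33 ± 0.07). The call of Uqcr10 was lost without 14 of the animals (adjusted p up to 0.119, without WT normal replicate 3). Erythroid markers, of which haemoglobin genes report blood in the tissue, were lower in CCM hearts (8 measured, none changed, 7 fell adjusted over the list alone, median -0.58), at a camera adjusted p of 1.59e-07 and adjusted p = 0.160 with an estimated correlation. Extracellular matrix genes were shifted higher (30 measured, none changed, adjusted p = 0.00333, and adjusted p = 0.413 with an estimated correlation), a call lost without WT normal replicate 2 (adjusted p = 0.0767). Interferon genes (17 measured, adjusted p = 0.00389) and macrophage markers (11 measured, adjusted p = 0.0163) were shifted lower with none changed. Neither held with an estimated correlation (adjusted p = 0.523 and 0.569) or without WT normal replicate 5 (0.0821 and 0.168).

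For the normal diet, 8 lists passed with the preset correlation and 1 with the estimated one. Dividing the log2 values of each array so that their medians were equal over all probes gave 155 changed genes, and the animals numbered under 20 and over 20 gave 84 and 86 when fitted alone. Across all genes the effects in these parts correlated with an r of 0.0074. All 282 genes called over all animals had the same sign in both parts, though calls made on both parts together favour this. Blocking on these parts gave 363.

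On the high fat diet, CCM and WT hearts differed in many of the same genes. Clock was at least 268-fold higher by the same probe (8.07 ± 0.38 log2, adjusted p = 5.94e-11), while the other detected Clock probe showed 0.48 log2. Ces1d was 11.8-fold lower (-3.57 ± 0.14 log2, adjusted p = 4.90e-12) and Dgat2 was 2.28-fold lower (-1.19 ± 0.10 log2, adjusted p = 6.12e-07). Dbp fell by 1.62 ± 0.16 log2 (adjusted p = 4.12e-06) and Bdh1 was 2.82-fold lower (adjusted p = 0.000208). The other bright Bdh1 probe showed -1.62 and the dim one 0.26. In all, 288 genes changed by limma, 127 higher and 161 lower in CCM, 77 of them at least 2-fold. The other large increases were AmpR (at least 13.2-fold), AlkPhos (at least 7.39-fold), Slc17a7 (1.64 ± 0.23 log2), Mrln (1.55 ± 0.19) and the heat shock protein gene Hspa1l (2.84-fold). The other large decreases were Laptm4a (-2.89 ± 0.14), Cyp2b10 (-2.78 ± 0.31), Amy1 (-2.54 ± 0.16), Amy2a5 (-2.41 ± 0.13) and Ano4 (at least 3.44-fold lower).

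Of the 18 core clock genes, 3 rose, 2 fell and 13 did not pass on the high fat diet (5 rose and 5 fell adjusted over the list alone), and the list did not pass (adjusted p = 0.592, median -0.17, mean 0.27). Here too Clock, at 8.07 log2, is a member that raised the mean and counted against a lower list. Arntl rose by 0.76 ± 0.17 log2 (adjusted p = 0.0168) and the orphan receptor gene Rorb by 0.60 ± 0.14. Ciart was at least 1.74-fold lower. Per3 (-0.53 ± 0.17, adjusted p = 0.166) and Cry2 (-0.65 ± 0.20, adjusted p = 0.138) did not pass. With the block on animal numbers Cry2 passed (-0.61, adjusted p = 0.0405). The Arntl call was lost without CCM high fat replicate 4 (adjusted p = 0.0503) or WT high fat replicate 4 (0.0755). The call of Rorb was lost without 7 single animals (up to 0.129, without WT high fat replicate 4). Of the PAR bZIP and clock-output list, 5 of 12 fell, none rose and 7 did not pass (7 fell adjusted over the list alone), at a camera adjusted p of 1.06e-13 and adjusted p = 0.000535 with an estimated correlation. These were Dbp, Tef (-1.42 ± 0.12, with -1.33 and 0.16 for its dimmer probes), Nampt (-1.20 ± 0.19), Usp2 (-0.82 ± 0.20, adjusted p = 0.0408) and Dgat2. Without Dgat2 the unadjusted p was 2.07e-05. The call of Usp2 was lost without 12 single animals (adjusted p up to 0.171, without WT high fat replicate 1).

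Lipid genes on the high fat diet gave 1 fall (Dgat2) among 15 triglyceride synthesis genes, also adjusted over the list alone, and no call for the list (adjusted p = 0.556). Agpat3 stood at 0.17 ± 0.08 (adjusted p = 0.454), Pnpla3 rose (0.83 ± 0.19), and the droplet coat gene Plin4 fell (-0.45 ± 0.10). Pmvk fell by 0.88 ± 0.11. The hexokinase gene Hk1 rose by 0.30 ± 0.08, a call lost without 17 single animals (adjusted p up to 0.173, without WT high fat replicate 1), and another, dim probe of it showed 0.12. Ketone and branched-chain amino acid catabolism was lower (3 of 21 fell, none rose, 4 fell adjusted over the list alone, adjusted p = 8.86e-05, and adjusted p = 0.0688 with an estimated correlation). Its falls were Bdh1 and the branched-chain dehydrogenase subunits Dbt (-0.49 ± 0.09) and Bckdhb (-0.47 ± 0.10). Fatty acid oxidation was lower in CCM on this diet (1 of 24 fell, 2 adjusted over the list alone, adjusted p = 0.0193, and adjusted p = 0.255 with an estimated correlation). So were PPAR alpha targets (21 measured, 1 rose and 1 fell, 1 and 3 adjusted over the list alone, adjusted p = 0.0468, and adjusted p = 0.572 with an estimated correlation). Ehhadh, a peroxisomal oxidation enzyme, fell by 0.55 ± 0.12. Fgf21, a fasting-induced hormone, rose by 0.95 ± 0.21 and was detected in 5 of 5 CCM and 2 of 4 WT hearts. Single animals ended the calls of PPAR alpha targets (8 animals, adjusted p up to 0.214 without WT high fat replicate 2), fatty acid oxidation (2, up to 0.0776 without CCM high fat replicate 4). The same was true of Plin4 (5, up to 0.0908 without WT high fat replicate 1), Pnpla3 (3, up to 0.0594 without CCM high fat replicate 2), Bckdhb (2, up to 0.0675 without WT high fat replicate 4), Fgf21 (2, up to 0.0870 without the same animal) and Ehhadh (0.0570 without WT high fat replicate 3).

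Cardiac stress genes were higher in CCM on the high fat diet, with 5 of 24 risen, none fallen and 19 not passing (9 rose adjusted over the list alone), at a camera adjusted p of 1.44e-07 and adjusted p = 0.0277 with an estimated correlation. They included Nppb, the natriuretic peptide BNP gene (0.70 ± 0.17), skeletal actin Acta1 (0.68 ± 0.15), Rcan1 (1.09 ± 0.12), Xirp1 (0.60 ± 0.12) and Cdkn1a (1.19 ± 0.28). Proteasome subunits were shifted higher as a group (35 measured, none changed, 32 of positive sign, median 0.17, adjusted p = 2.69e-05, and adjusted p = 0.00576 with an estimated correlation). Heat shock genes were shifted higher as well (1 of 20 rose, 2 adjusted over the list alone, adjusted p = 2.69e-05, and adjusted p = 0.0799 with an estimated correlation), with Hsph1 at 0.62 ± 0.16 (adjusted p = 0.0487). Extracellular matrix genes were shifted higher with none of 30 changed (adjusted p = 0.0193, and adjusted p = 0.572 with an estimated correlation). Other risen genes were Trib3 (0.82 ± 0.13), Hcn2 (1.11 ± 0.12), Egr2, an early-response factor (1.05 ± 0.23), Mybpc3 (0.52 ± 0.10), Mybpc2 (0.87 ± 0.17), Mrps34 (0.33 ± 0.07) and Mrpl54 (0.40 ± 0.10). Ier3 (-0.99 ± 0.13), smooth muscle actin Acta2 (-0.69 ± 0.17), Mrpl22 (-0.69 ± 0.10) and Uqcr10 (-0.32 ± 0.07) fell. Without WT high fat replicate 4 the adjusted p rose to 0.141 for Cdkn1a, 0.160 for Nppb, 0.0845 for Acta1, 0.159 for Hsph1, 0.0815 for Mrps34, 0.184 for Mrpl54 and 0.153 for the matrix genes. Other animals ended the calls of Egr2 (0.0730 without WT high fat replicate 1), Acta2 (0.158 without WT high fat replicate 2) and Uqcr10 (0.0720 without WT high fat replicate 3).

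Of the named calls for this diet, 28 of 46 held without any single animal, against 34 of 40 on the normal diet. Of the lists, 8 passed with the preset and 3 with an estimated correlation, 5 passed without CCM high fat replicate 4 and 13 without CCM high fat replicate 2. With arrays scaled to equal medians over all probes, 183 genes changed (49 higher, 134 lower), without the 3 arrays of lowest mean signal 180, and in the animals numbered under 20 and over 20 alone 90 and 47. Across all genes the effects in these parts correlated with an r of 0.596. All 288 genes called over all animals had the same sign in both parts, with the same limit. Blocking on these parts gave 394.

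Across all genes the genotype effects on the 2 diets correlated with a Pearson r of 0.619 (jackknife error 0.149 over animals) and a Spearman rho of 0.339, genes not being independent replicates. Of the calls, 186 were shared between the diets, 69 higher and 117 lower, and all 186 had the same sign. Independent lists would share 0.938 and 1.89. Of the genes called on the normal diet, 276 of 282 had the same sign on the high fat diet, and 287 of 288 in the other direction. The r was 0.196 in the animals numbered under 20 alone and 0.461 in those over 20. On either diet 3 CCM animals were numbered under 20 and 2 over 20. In WT these numbers were 2 and 3 on the normal diet and 2 and 2 on the high fat diet. The animal number structure described below thus enters both genotype effects in the same direction and can add to their r and to the shared calls.

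**Figure D2:**
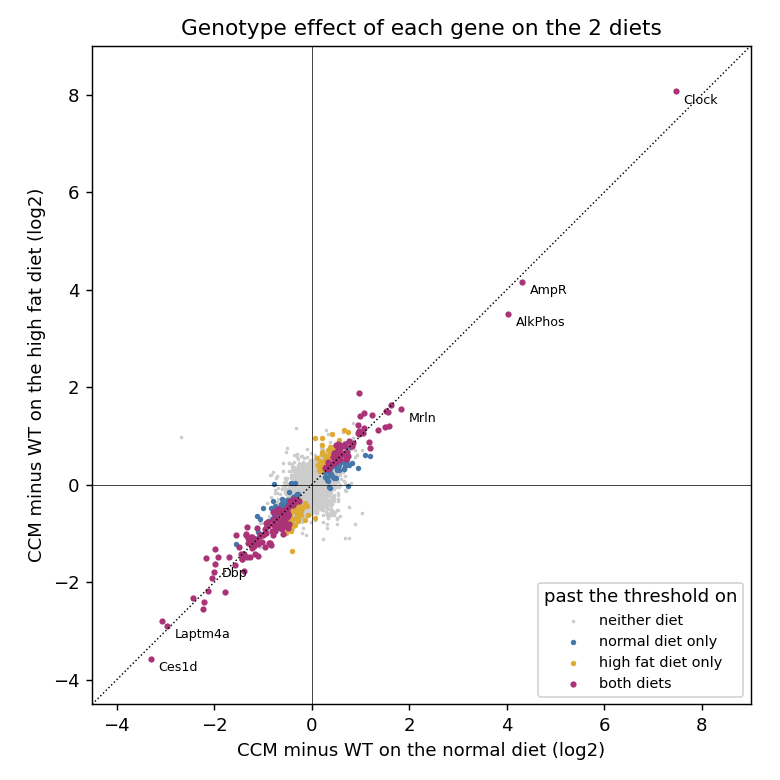
Each point is 1 of 14762 genes, with its CCM minus WT difference (log2) on the normal diet (horizontal axis) and on the high fat diet (vertical axis), coloured by the diet on which it passed the threshold. The 186 genes that passed on both diets had the same sign on both and lay along the dotted line of equal effects.

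Averaged over the diets, 743 genes differed by genotype (355 higher, 388 lower), and 11 of 18 core clock genes were among them. Arntl (0.98 ± 0.11), Rorb (0.47 ± 0.10), Nr1d1 (0.41 ± 0.10), the casein kinase gene Csnk1d (0.33 ± 0.07) and Clock were the 5 that rose. Among the 6 that fell were Ciart (at least 1.92-fold lower), Nr1d2 (-0.91 ± 0.21), Cry2 (-0.71 ± 0.14), Per3 (-0.66 ± 0.12) and Csnk1e (-0.30 ± 0.08). In this list 5 rose and 7 fell adjusted over the list alone. The other detected probe of Clock showed 0.48, another probe of Nr1d2 showed -0.26, and other probes of Csnk1d showed 0.34, 0.12 and 0.10. Of the 12 clock-output genes 7 fell (8 adjusted over the list alone), Tspan4 (-0.39 ± 0.09), Por (-0.27 ± 0.08) and Usp2 (-0.75 ± 0.14) among them, at an adjusted p of 1.16e-14 and adjusted p = 0.000366 with an estimated correlation. Dgat2 fell by 1.17 ± 0.07 (adjusted p = 1.19e-09) and Agpat3 rose by 0.30 ± 0.05. Single animals ended the calls of Csnk1e (9 animals, adjusted p up to 0.0793) and Por (14, up to 0.108, both without WT high fat replicate 1).

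In the averaged effect, Bdh1 (-1.83 ± 0.14), Dbt (-0.38 ± 0.06), Bckdhb (-0.34 ± 0.07), Oxct1 (-0.27 ± 0.06) and the valine catabolism gene Hibadh (-0.19 ± 0.05) were the 5 falls among 21 ketone and branched-chain genes (5 adjusted over the list alone, adjusted p = 0.000628, and adjusted p = 0.131 with an estimated correlation). Ehhadh (-0.40 ± 0.08), Eci1 (-0.23 ± 0.06) and Ech1 (-0.24 ± 0.06) were the 3 falls among 24 fatty acid oxidation genes (5 adjusted over the list alone, adjusted p = 0.0299, and adjusted p = 0.289 with an estimated correlation). Cardiac stress genes gave 7 rises and no fall (11 rises adjusted over the list alone, adjusted p = 3.19e-07, and adjusted p = 0.0330 with an estimated correlation), with Nppb (0.61 ± 0.12), Acta1 (0.44 ± 0.10), Xirp2 (0.35 ± 0.09) and Uck2 (0.48 ± 0.09). Matrix genes gave 3 rises among 30 (4 adjusted over the list alone, adjusted p = 0.000971, and adjusted p = 0.315 with an estimated correlation), which were Tgfb2 (0.58 ± 0.15), Loxl1 (0.33 ± 0.09) and Col8a1 (0.49 ± 0.14). Among early-response genes Egr1 (0.52 ± 0.14), Egr2 (0.73 ± 0.16), Egr3 (0.59 ± 0.15), Atf3 (0.77 ± 0.21) and Ccn1 (0.45 ± 0.12) rose. Ier3 fell by 0.96 ± 0.09 and Pik3r1 fell by 0.49 ± 0.07. Proteasome subunits were shifted higher (1 of 35 rose, 1 adjusted over the list alone, adjusted p = 0.000154, and adjusted p = 0.0121 with an estimated correlation). Heat shock genes were shifted higher (1 of 20 rose, 2 adjusted over the list alone, adjusted p = 0.00168), with adjusted p = 0.216 with an estimated correlation. Glucose and glycogen genes (1 of 34 rose and 3 fell, likewise adjusted over the list alone, adjusted p = 0.00704) and erythroid markers (none of 8 changed, 6 fell adjusted over the list alone, adjusted p = 0.000154) were shifted lower. These had adjusted p = 0.315 and 0.216 with an estimated correlation. Without WT normal replicate 2 the fatty acid oxidation list had an adjusted p of 0.0749, and 5 single animals ended its call.

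Across the averaged genotype calls, 12 of the 38 named genes lost the threshold without at least 1 animal, among them Hibadh (adjusted p up to 0.0797), Xirp2 (0.0797), Tgfb2 (0.0735), Loxl1 (0.0698), Col8a1 (0.108), Egr3 (0.0748) and Ccn1 (0.103), each highest without WT high fat replicate 4. The others were Ech1 (0.0580) and Egr1 (0.0663) without WT high fat replicate 1 and Atf3 (0.0711) without CCM normal replicate 1. A dimmer Egr3 probe showed 0.01. Arrays scaled to equal medians over all probes gave 418 genes.

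In WT hearts on the high fat diet, Pdk4, which inhibits pyruvate oxidation (1.89 ± 0.29 log2, adjusted p = 0.0151), Fbp2, the muscle fructose bisphosphatase (1.19 ± 0.18, adjusted p = 0.0151), the lipid droplet gene Cidea (0.73 ± 0.13, adjusted p = 0.0476) and Mgll, monoglyceride lipase (0.46 ± 0.08, adjusted p = 0.0476), rose. They and 2210409D07Rik were among 6 genes called by limma, all higher. Angptl4, an inhibitor of lipoprotein lipase (2.86 ± 0.53, adjusted p = 0.0675), Ucp3 (1.49 ± 0.28, adjusted p = 0.0677) and Agpat3 (0.41 ± 0.08, adjusted p = 0.0675) did not pass. A dim second probe of Pdk4 showed -0.13. Dgat2 stood at 0.10 ± 0.10 and did not pass, and none of the 18 core clock genes passed in either genotype.

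PPAR alpha targets were shifted higher as a list in WT on the high fat diet: 2 of 21 rose, none fell and 19 did not pass (13 rose adjusted over the list alone), at a camera adjusted p of 1.45e-30 and adjusted p = 0.000229 with an estimated correlation. Fatty acid oxidation genes were shifted higher (none of 24 changed, 10 rose adjusted over the list alone, adjusted p = 3.13e-17, and adjusted p = 0.000229 with an estimated correlation). So were those of fatty acid uptake and activation (none of 15 changed, 1 rose adjusted over the list alone, adjusted p = 0.000556, and adjusted p = 0.00686 with an estimated correlation). That list includes Angptl4 (2.86 log2), an inhibitor of lipoprotein lipase, so its shift does not by itself show a rise of uptake genes. Triglyceride synthesis (none of 15 changed, 2 rose adjusted over the list alone, adjusted p = 0.00259) and lipid droplet genes (2 of 17 rose, 3 adjusted over the list alone, adjusted p = 0.00259) were shifted higher with the preset correlation. They had adjusted p = 0.0920 and 0.158 with an estimated correlation. The other lists that passed with the preset correlation alone held no changed gene. Interferon genes (adjusted p = 0.00114, and 0.422 with an estimated correlation), heat shock genes (0.00297 and 0.231) and ion channels (0.00739 and 0.0760) were lower. Matrix genes (0.00294 and 0.422), endothelial markers (0.0128 and 0.231) and adipocyte markers (0.0325 and 0.422) were higher. Single animals ended each of these 6 calls, with adjusted p up to 0.127 for interferon genes (without WT high fat replicate 1), 0.184 for heat shock genes and 0.173 for adipocyte markers (without WT normal replicate 1), 0.0689 for ion channels (without WT high fat replicate 3), 0.482 for matrix genes (without WT high fat replicate 2) and 0.103 for endothelial markers (without WT normal replicate 2).

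The diet count in WT was small and moved with single animals: 2 genes changed without WT high fat replicate 1, 2 or 3 or WT normal replicate 5, and 3 without WT normal replicate 1. Adjusted p values without WT high fat replicate 3 were 0.124 for Pdk4, 0.103 for Fbp2 and 0.285 for Cidea and Mgll. Without CCM normal replicate 4, which enters through the shared spread, Angptl4 passed (adjusted p = 0.00700), and Ucp3 passed without WT high fat replicate 4 (0.0133). Blocking on animals numbered under and over 20 gave 10 genes, including Angptl4 (2.94, adjusted p = 0.0228), Agpat3, Lgals4 and Tnnt1 (-0.64), and array weights gave 19.

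In CCM hearts the high fat diet raised Fgf21 (at least 1.94-fold, adjusted p = 0.0148) and Aqp8, a water channel (1.10 ± 0.18, adjusted p = 0.0387), and lowered Gcat, a mitochondrial enzyme of threonine breakdown (-0.56 ± 0.09, adjusted p = 0.0214). They were among 4 genes called by limma, 3 higher and 1 lower. Pdk4 (0.94 ± 0.28, adjusted p = 0.501), Angptl4 (2.27 ± 0.50, adjusted p = 0.194), Cidea (0.67 ± 0.12, adjusted p = 0.0629) and Dgat2 (0.07 ± 0.10, adjusted p = 0.816) did not pass. CCM normal replicate 4 lay apart from its group in Pdk4 (14.10 against 12.55 to 12.75) and Angptl4 (9.81 against 7.03 to 7.53), and without it Angptl4 passed (adjusted p = 0.0194).

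PPAR alpha targets were shifted higher in CCM too (2 of 21 rose, none fell, 8 rose adjusted over the list alone, adjusted p = 1.43e-14, and adjusted p = 0.0155 with an estimated correlation). Fatty acid oxidation genes were shifted higher as a list (none of 24 changed, 6 rose adjusted over the list alone, adjusted p = 1.25e-06, and adjusted p = 0.0251 with an estimated correlation). Triglyceride synthesis genes were shifted higher (none of 15 changed, 4 rose adjusted over the list alone, adjusted p = 0.0170, and adjusted p = 0.250 with an estimated correlation). Erythroid markers were higher on the high fat diet (none of 8 changed, 1 rose adjusted over the list alone, median 0.23, adjusted p = 0.000104, and adjusted p = 0.250 with an estimated correlation). Cardiac stress genes (none of 24 changed, 3 rose adjusted over the list alone, adjusted p = 0.00407, and adjusted p = 0.250 with an estimated correlation) and interferon genes (none changed, adjusted p = 0.0164, and 0.690 with an estimated correlation) were shifted higher. Adipocyte markers (0.0223 and 0.488) and ion channels (0.0258 and 0.202) were shifted lower. Single animals ended the calls of triglyceride synthesis (adjusted p = 0.0786) and cardiac stress genes (0.0560, both without CCM normal replicate 5), interferon genes (up to 0.372, without CCM high fat replicate 3), adipocyte markers (up to 0.299, without CCM normal replicate 4) and ion channels (up to 0.101, without CCM high fat replicate 4).

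No gene stayed called in CCM without CCM high fat replicate 4, CCM normal replicate 1 or CCM normal replicate 3, 2 did without CCM high fat replicate 2, and 8 were called without CCM high fat replicate 5 or WT high fat replicate 4. At unadjusted p under 0.05 limma gave 1294 genes in this comparison, where 738 are expected by chance. For the diet effect in WT it gave 457, under that number, so the excess in CCM is no measure of a broader response. The adjusted p was 0.110 for Gcat without CCM normal replicate 1, 0.153 for Aqp8 without CCM high fat replicate 4 and 0.0822 for Fgf21 without CCM normal replicate 3. Cidea passed without WT high fat replicate 4 (adjusted p = 0.0377). Blocking on animals numbered under and over 20 gave 10 genes, among them Fbp2 (0.90, adjusted p = 0.0345), Cidea, Trib3 and Tnnt1 (-0.59), array weights gave 12, and arrays scaled to equal medians over all probes gave 1 (1 higher, 0 lower). The number of lists was 8, and it was 4 without CCM normal replicate 5, 5 without CCM high fat replicate 3 or CCM normal replicate 4, and 13 without CCM normal replicate 3.

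Averaged over the genotypes, the high fat diet changed 45 genes, 37 higher and 8 lower. Angptl4 rose by 2.57 ± 0.37 log2 (adjusted p = 0.00244), Pdk4 by 1.41 ± 0.20, Fbp2 by 1.05 ± 0.13 and the mitochondrial carrier gene Ucp3 by 1.03 ± 0.20. Fgf21 was at least 1.44-fold higher. Slow skeletal troponin Tnnt1 (-0.62 ± 0.08), the GABA transaminase gene Abat (-0.62 ± 0.10), Whrn (-0.57 ± 0.10), Prokr1 (-0.44 ± 0.09), Prps2 (-0.42 ± 0.09) and Septin6 (-0.42 ± 0.08) fell. Of 21 PPAR alpha targets 8 rose and none fell (15 rose adjusted over the list alone, adjusted p = 8.24e-28, and adjusted p = 0.000465 with an estimated correlation), including the thioesterase Acot2 (0.99 ± 0.18) and the droplet coat gene Plin2 (0.67 ± 0.14). Of 24 fatty acid oxidation genes, Decr1 (0.52 ± 0.08) and Eci1 (0.32 ± 0.06) rose and none fell (11 rose adjusted over the list alone, adjusted p = 3.48e-15, and adjusted p = 0.000465 with an estimated correlation). Glycerol kinase Gk (0.41 ± 0.08) and Agpat3 (0.27 ± 0.05) were the 2 rises among 15 triglyceride synthesis genes (5 adjusted over the list alone, adjusted p = 0.00176, and adjusted p = 0.0788 with an estimated correlation). Cidea (0.70 ± 0.09), Mgll (0.36 ± 0.06) and Trib3 (0.52 ± 0.09) rose. Ion channel genes were shifted lower with none of 29 changed (adjusted p = 0.00299, and adjusted p = 0.0393 with an estimated correlation).

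**Figure D3:**
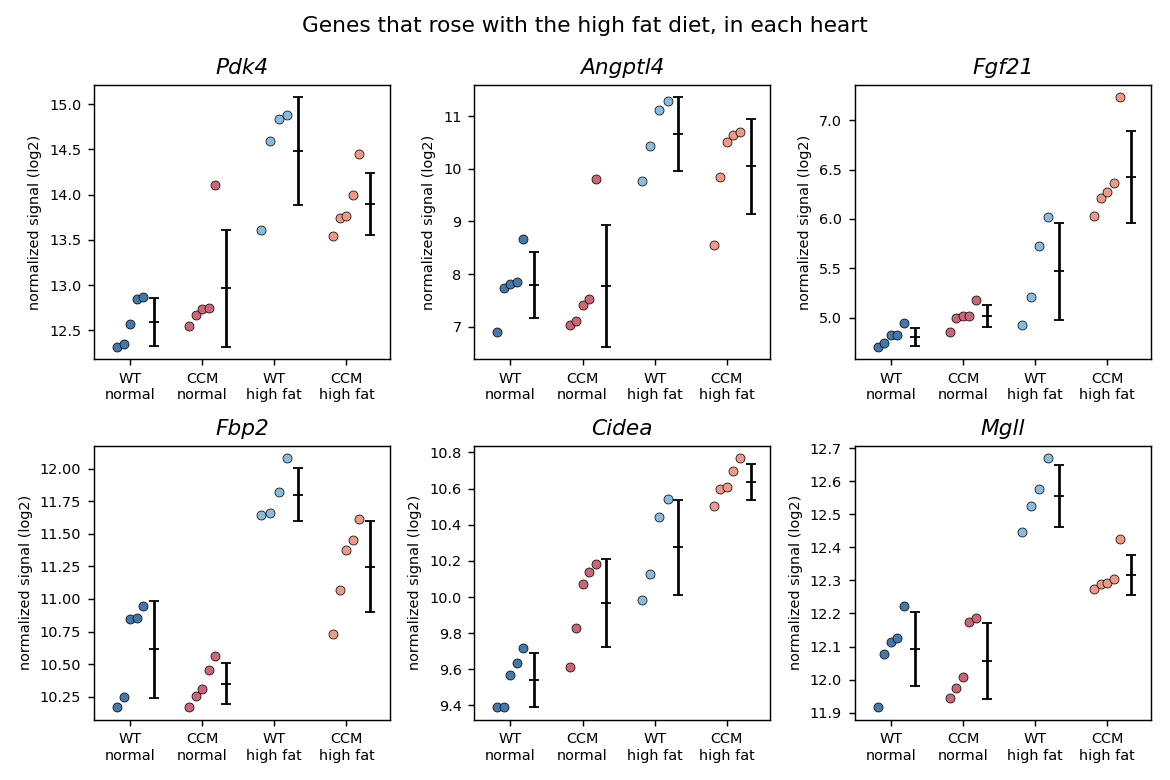
Normalized signal (log2, vertical axes) of 6 genes that rose with the high fat diet, in each of 19 hearts by genotype and diet, with the mean and SD of each group beside the points. In CCM hearts on the normal diet 1 animal lay above the other 4 in Pdk4 (14.10) and Angptl4 (9.81).

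The averaged diet count was 28 without CCM normal replicate 1, 23 without WT high fat replicate 2, 22 without WT high fat replicate 3 and 68 without CCM normal replicate 5. It was 17 (16 higher, 1 lower) with arrays scaled to equal medians over all probes, 15 without the 3 arrays of lowest mean signal, 201 (127 higher, 74 lower) with array weights and 68 with the block on animal numbers. Without WT high fat replicate 2 the adjusted p was 0.0730 for Ucp3, 0.136 for Plin2, 0.0664 for Gk and 0.0741 for Agpat3. Without WT high fat replicate 3 it was 0.0602 for Acot2, 0.0850 for Prokr1, 0.140 for Prps2 and 0.0976 for Septin6. A dim second probe of Pdk4 showed -0.03, and dim probes of Angptl4 (0.62) and Acot2 (0.19) showed smaller values. Other probes of Gk showed 0.42 and, detected on 5 arrays, 0.06. Further lists passed with the preset correlation alone and held no changed gene, apart from fatty acid uptake and activation, where 1 of 15, the lipoprotein lipase inhibitor Angptl4, rose (1 adjusted over the list alone, adjusted p = 0.0301). That list had adjusted p = 0.0869 with an estimated correlation and 0.221 without CCM normal replicate 5. Matrix genes (adjusted p = 0.00387, and 0.445 with an estimated correlation), cardiac stress genes (0.00472 and 0.257), erythroid markers (0.00864 and 0.445) and endothelial markers (0.0110 and 0.242) were shifted higher. The call of the matrix genes was lost without WT high fat replicate 2 (adjusted p = 0.0602). The diet effects in the 2 genotypes correlated across genes with a Pearson r of 0.368, and they shared 1 call.

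No gene passed for the interaction of genotype and diet in limma, in which 401 genes had an unadjusted p under 0.05 where 738 are expected by chance. The difference of the diet effects, CCM minus WT, was -0.95 ± 0.40 log2 for Pdk4 and -0.03 ± 0.14 for Dgat2, neither of which passed. A diet call in 1 genotype alone is thus no evidence that the genotypes differed in their response. With the preset correlation 5 lists passed for the interaction, and none did with an estimated correlation. Adipocyte markers differed most in size (8 measured, all of negative sign, median -0.79, adjusted p = 9.68e-05), with adjusted p = 0.214 with an estimated correlation. The number of lists was 8 without CCM high fat replicate 2 or WT normal replicate 1.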

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

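The tests of animal numbers, the block on them, the fits without the 3 arrays of lowest mean signal the constant shift of each array, the shuffled order of animals and the share of changed genes per chromosome were chosen only after the result was seen.

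Within groups, 2253 genes differed between the 10 animals numbered under 20 and the 9 numbered over 20 (1033 higher and 1220 lower over 20), a division chosen after seeing the data. For this division taken alone chance was unlikely (1 of 100 random splits within groups, the real one, gave as many, highest other 16). With the choice of the best of 15 divisions allowed for, 2 of 100 shuffled orders of the animals, the real one included, reached as many. The other of these orders gave more genes than the real one (2659), so chance is unlikely but not excluded. Low brightness of single arrays was argued against by 3410 genes without the 3 arrays of lowest mean signal, and quantile normalization by 2408 genes with a constant shift of each array in its place (4854 with median scaling, which can itself stretch arrays apart). The count moved between 1501 and 3013 without single animals, and of the 15 divisions this one gave the most genes, the adjoining ones 1427 and 1369, and 7 of them 0. What the numbers stand for, such as a day, a slide or a litter, is not given in the sources used here. None of 36 gene lists passed between the parts by camera with an estimated correlation (smallest adjusted p = 0.965). The preset correlation, with which more lists passed in every comparison, was not run for the parts, so smaller shifts of lists are not excluded. The cause stays open.

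The probes named AmpR and AlkPhos read 9.27 ± 0.20 and 8.61 ± 0.31 (SD, n = 10) in CCM hearts and were detected in no WT heart. A raised background of foreign-sequence probes was argued against, since the probes named NeoR, GFP and Cre had a median CCM minus WT difference of -0.0068. A candidate explanation is sequence carried by the transgene, and a test of whether the summed probes followed Clock over the 10 CCM animals left it open (Pearson r = -0.520, permutation p = 0.123, Spearman rho = -0.622, permutation p = 0.0598, two-sided). Without the 2 animals farthest from the median of Clock, r was -0.188, and within the diets it was -0.343 and -0.061. The Clock probe lay near the top of the signal range in CCM, which limits that test.

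Among the genes changed by genotype averaged over diets, 40 pairs of neighbouring measured genes changed in the same direction, against a median of 19 in random lists of the same size (11 to 28 in the central range, highest 37, 0 of 10000 with as many). This is what linked chromosome segments would show, but local clusters of related or co-regulated genes, and paralogs that share probes, could give such pairs too and were not separated. A single segment that holds most changes was argued against, since no chromosome held over 7.52% of the 665 changed genes with a position, and the pairs lay on 18 chromosomes with at most 5 on 1. The strain history of the CCM line was not tested and stays open.

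In a number of groups 1 animal stood far from the others of its group, by the gap to its nearest neighbour as a share of the group's range. This held in 25 of 384 groups of values, where chance alone gives 19.2 at about 1 in 20. CCM normal replicate 4 stood apart in Pdk4 (14.10), Angptl4 (9.81) and Ucp3 (5.94), and CCM normal replicate 1, 2 and 5 in Decr1 (10.54), Nampt (8.08) and Cyp2b10 (6.71). In WT on the normal diet replicate 1 stood apart in Nr1d2 (8.07) and Trib3 (7.01), replicate 2 in Cry2 (7.92), replicate 4 in Clock (6.16) and replicate 5 in AmpR (4.79), Ano4 (6.85) and Uck2 (11.75). In WT on the high fat diet replicate 1 stood apart in Eci1 (13.23), replicate 2 in Pik3r1 (11.82) and Decr1 (11.45), replicate 3 in Xirp1 (11.26) and Rorb (6.07), and replicate 4 in Pdk1 (10.15) and Whrn (10.47). In CCM on the high fat diet replicate 1 stood apart in Aqp8 (6.06), replicate 2 in Fgf21 (7.23), replicate 3 in Tgfb2 (10.40), replicate 4 in Mgll (12.42) and replicate 5 in Egr3 (8.12).

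For the interaction of genotype and diet, 5 lists passed by camera with a preset correlation. Of 100 splits of the animals, the real one included, 30 gave as many lists, so chance cannot be excluded. Interferon and antigen presentation genes (median 0.44, adjusted p = 6.55e-07), erythroid markers (0.32, 0.000281), heat shock genes (0.21, 0.000424) and macrophage markers (0.30, 0.0126) moved up in CCM relative to WT, and adipocyte markers moved down (-0.79, 9.68e-05). With an estimated correlation none passed (adjusted p = 0.266, 0.266, 0.214, 0.667 and 0.214 in that order). The macrophage call was lost without 6 single animals (adjusted p up to 0.307, without WT high fat replicate 1). No gene of these lists passed.

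Other splits of the same animals were used to ask whether chance could give as many genes, with 100 splits for each comparison. Split counts here include the real split. Chance was unlikely to give the genotype effect on the high fat diet (288 genes, highest other 75, 1 split with as many) or averaged (743, highest other 292, 1 split). On the normal diet (282, highest other 297, 2 splits) it was unlikely as well, but not excluded, since another split gave more genes. The same holds for the diet effect in WT (6 genes, highest other 8, 3 splits), in CCM (4, highest other 2075, 3 splits) and averaged (45, highest other 1435, 3 splits). No correction over the comparisons was made. These splits were not drawn within the animal number parts, so they do not exclude a contribution of that structure, and the count in CCM was 0 without CCM high fat replicate 4, CCM normal replicate 1 or CCM normal replicate 3. For the interaction the real count was 0, so that all 100 splits gave as many whatever the data (highest other 2937), and nothing follows about chance. Splits with many times the real count point to a structure of the samples. The split with 297 genes followed the animal numbers in 10 of 10 animals, that with 2075 in 9 of 10 and that with 2937 in 14 of 19, while that with 1435 did so in 11 of 19. Blocked on the numbers, the real counts were 363 for the normal diet, 10 for the diet effect in CCM, 0 for the interaction and 68 for the averaged diet effect.

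For the number of lists past the threshold chance cannot be excluded in any comparison. The real and highest other numbers were 8 and 10 for the genotype effect on the normal diet (17 splits with as many), 8 and 11 on the high fat diet (21) and 9 and 11 averaged (11). They were 11 and 13 for the diet effect in WT (7), 8 and 12 in CCM (8), 9 and 12 averaged (9), and 5 and 12 for the interaction (30).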

How the results depend on the processing

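The fits with the animal number block, within each animal number part, without the 3 arrays of lowest mean signal and with equal medians of detected probes were chosen after seeing the data. A fit with slide as a block was not run, because the files give no slide. No paired analysis was possible because each animal number occurs once. Signal over background and the number of arrays limit what can be called. The cause of the moves below was not tested, except that fits on fewer animals have fewer samples.

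With median scaling, which divides log2 values, 155 genes changed for the genotype effect on the normal diet, 183 on the high fat diet and 418 averaged, and 3, 1 and 17 for the diet effect in WT, in CCM and averaged. A constant shift of each array to equal medians of detected probes gave 258, 257 and 715 for the genotype effects. Animals numbered under 20 alone gave 84, 90, 249, 0, 0 and 2 genes in that order, and those over 20 gave 86, 47, 203, 0, 0 and 0. Without the 3 dimmest arrays the genotype effect on the high fat diet gave 180, and the diet effect 2 in WT and 15 averaged. Fits of only the 2 groups compared gave 177 for the genotype effect on the normal diet and 1 and 2 for the diet effect in WT and CCM. The diet effects in WT and CCM gave 11 and 7 genes without background correction, 11 and 8 with an offset of 50, 11 (9 higher, 2 lower) and 7 (6 higher, 1 lower) with the authors' values, 19 and 12 with array weights, and 10 and 10 with the animal number block. In WT trended, robust eBayes gave 10. In CCM no detection filter gave 2, detection on all 19 arrays 2, and equal medians of detected probes 7. The averaged diet effect gave 201 with array weights and 68 with the block.

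With an estimated correlation 1, 3, 3, 3, 2, 3 and 0 lists passed for the genotype effect on the normal diet, on the high fat diet and averaged, the diet effect in WT, in CCM and averaged, and the interaction. Animals over 20 gave 4 lists for diet in WT and animals under 20 gave 3 for diet in CCM, where array weights gave 5. The interaction gave 9 lists at detection p under 0.01, 9 without the 3 dimmest arrays, 10 with equal medians of detected probes and 0 in animals under 20. The correlation of the genotype effects was 0.196 under 20, 0.461 over 20 and 0.966 among genes changed in the averaged effect, a choice of genes that favours a high value by construction.

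Without single animals the lists numbered 5 to 13 for the genotype effect on the high fat diet, 4 to 13 for diet in CCM and 4 to 8 for the interaction. Genes numbered 2 to 7 for diet in WT, 0 to 8 in CCM and 22 to 68 averaged. The genotype counts stayed between 213 and 277 on the normal diet, 209 and 318 on the high fat diet and 621 and 731 averaged.

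Of 151 named calls, 41 kept the threshold in every setting. Of 5795 alternative values for named genes 4943 kept their side and direction, 803 lost the threshold, 40 gained it and 9 reversed, none of these 9 a called value. Dgat2 reversed for diet in WT under 20 (-0.011) and for diet in CCM over 20 (-0.012) and without the 3 dimmest arrays (-0.0042). Per1 on the normal diet reversed with array weights (0.017), over 20 (0.94), without the 3 dimmest arrays (0.14) and without CCM normal replicate 1 (0.04), CCM normal replicate 3 (0.12) or WT normal replicate 1 (0.14), and it ranged from -0.46 to 0.14 without single animals.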

Other observations

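The tests of all ATF4 targets together were chosen only after the result was seen.

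Trib3, Fgf21 and Atf3, known targets of the stress-response factor ATF4, were higher in CCM or on the high fat diet. A hypothesis drawn from this was that ATF4 targets may rise together, and it was tested on the 20 measured targets that had not been seen before, with all 11 measured targets already seen, these 3 among them, set aside. Their median was 0.04 for the genotype effect averaged over diets (1 rose, none fell, 15 of 20 of positive sign, camera p = 0.270 with an estimated correlation) and 0.04 for the averaged diet effect (13 of 20, p = 0.130). All 31 measured targets together (7 rose and none fell by genotype, 4 and none by diet) gave camera p-values of 0.00185 and 0.000999. They include the genes that prompted the test. Setting aside the targets already seen left out most of those that rose (by genotype 7 of all 31 rose, but 1 of the 20). The test on the 20 was thus tilted against a rise. The bound written beforehand counted a p of 0.05 or more against the hypothesis, which was wrong, since a missed threshold does not exclude a smaller rise. The hypothesis stays open.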
